A study of Homo sapiens with 9 samples.

How the data were processed

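Gene expression was measured on 9 one-colour Affymetrix arrays, 1 per RNA sample of HEK293 cells, a human line derived from embryonic kidney. Per the labels' protocols, the growth medium is given only as 10% DMEM, siRNA was delivered by calcium phosphate transfection, total RNA was purified on spin columns with DNase digestion on the column, and biotin-labelled target was made with a MessageAmp II kit. The titles place 3 arrays in each of 3 groups, named siControl, siPIPKIa and siStarPap, with replicate numbers 4, 5 and 6. Nothing in the labels says that the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

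The deposited table gives 1 intensity on a linear scale for each of 54675 probe sets and each array. The summary, background and normalization methods are not given in the sources used here. The values were from 4.588 to 28844, and 100% of those above 100 lay within 5e-05 of a log2 value with 3 decimals, so they are antilogs of rounded log2 values. The mean after trimming 2% from each end was between 302.51 and 312.34 on the 9 arrays. The table was therefore taken as already normalized and was not scaled again. It holds no detection calls, so signal over background could not be separated per probe set, and the number of arrays limits the precision. No pair of arrays held more than 4.21% identical values, and each was counted as 1 sample.

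The 62 control probe sets were left out of the tests. Gene names came from the platform annotation, updated through the gene ID with a RefSeq table of assembly GRCh38.p14, from which no coordinates were taken. Of the probe sets, 41037 matched by ID. One symbol was given for 41091 probe sets, several for 1801 and none here for 11721, and no gene was named from a probe set with several. Intensities were turned into log2(intensity + 16). Fold changes are on that scale, which understates the change of dim genes. Probe sets below the 40th percentile of mean signal, an intensity of 43.13, were removed, and the brightest remaining probe set stood for each gene. Of 19775 genes with a probe set, 14626 were tested. Where the probe sets of a gene disagree, the brightest decides the value. Probe sets ending in _s_at or _x_at can hybridise with several transcripts, and values of histone and ribosomal protein genes, which have near-identical copies, are uncertain for that reason. The targeted genes were followed on all of their probe sets, in a fit of all 54613 non-control probe sets.

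All 9 arrays entered 1 linear model with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 6 residual and 5.04 prior degrees of freedom), and p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. A comparison of 3 with 3 arrays cannot give an exact two-sided p below 0.1, so single-gene permutation tests were not used. Errors are standard errors of the fitted log2 differences unless called SD. A set of 34 gene lists with 736 members, of which 634 entries were tested, were fixed before the data were examined and compared with all other genes by camera with a preset correlation of 0.01. Camera with an estimated correlation and fry served as alternatives. Unlike camera, fry tests a list against no change and not against other genes, so it answers another question. For the overlap of the comparisons that share the control arrays, 100 data sets with unchanged groups were simulated. All 9 arrays, controls included, were drawn anew with noise independent between genes, and both comparisons shared the simulated control group.

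Named genes were chosen by a rule set before the data were examined. It takes the 10 largest rises and 10 largest falls for each siRNA against siControl among genes past the threshold whose arrays do not overlap, and 5 and 5 for the direct comparison. It adds the 5 strongest genes that rose in both, fell in both or moved apart, TUT1, PIP5K1A, HMOX1, NQO1 and GCLC, and up to 4 members of each list by smallest p. HMOX1 is named by the study itself, so its direction is not independent evidence.

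In simulated siStarPap against siControl data with 14626 genes, of which 200 changed, the model recovered 24.4% of genes changed 1.25-fold, 91.2% at 1.5-fold, 99.6% at 2-fold and 100% at 4-fold, with 5.75% false calls. A list of 21 genes shifted by -0.5 was recovered in 20 of 20 runs, with 2 false list calls.

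Alternatives were other pseudocounts, thresholds, filters and probe set rules, quantile normalization, median centring, an intensity trend with robust spread, array weights, the replicate number as a block, fits of only the groups compared, and leaving out each array in turn. The default array weight method did not converge on these arrays, and its gene-by-gene version was used. The 2-fold threshold was added after the data were examined.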

Results

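Transcript levels were compared between HEK293 cells given a control siRNA, an siRNA against PIPKIα or an siRNA against Star-PAP, with 3 arrays per group. PIPKIα, encoded by PIP5K1A, makes the lipid PIP2. Star-PAP, encoded by TUT1, is a nuclear poly(A) polymerase, and the series concerns a functional interaction of the 2 proteins. Arrays of one group correlated at r = 0.994 or above across probe sets. The array siControl 4 lay farthest from its group, with a root mean square deviation of 0.175 on the log2 scale, against 0.0987 and 0.114 for siControl 5 and siControl 6. The value for siStarPap 4 was 0.152. The bioB hybridisation control had a mean log2 signal from 9.24 to 9.41 on the arrays labelled siStarPap and from 9.10 to 9.12 on siControl arrays.

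The PIP5K1A transcript was lower on the siPIPKIa arrays by all 3 of its probe sets. Against siControl, the log2 differences were -0.88 ± 0.07 for the brightest (adjusted p = 3.4e-05), -1.16 ± 0.07 for the dimmest (adjusted p = 3.6e-06) and -1.12 ± 0.09 for the one between them (adjusted p = 2.0e-05), n = 3 per group, which left 0.544, 0.447 and 0.461 of the control level. The single TUT1 probe set was not lowered on the arrays labelled siStarPap. Its log2 level was 6.84 ± 0.09 (SD, n = 3) there, 6.93 ± 0.18 on siControl and 7.16 ± 0.10 on siPIPKIa arrays. The difference from siControl was -0.10 ± 0.09 (adjusted p = 0.52), or 0.936-fold with a 95% confidence interval from 0.806 to 1.09, so these arrays did not register the knockdown and every direction below is that of arrays so labelled. Without siControl replicate 4 that difference was -0.20 (limma adjusted p = 0.095), and without siControl replicate 5 it was -0.02 (0.91). TUT1 was lower than on the siPIPKIa arrays by a log2 difference of -0.32 ± 0.09 (adjusted p = 0.034). In the fit of 1 probe set per gene that last call was lost without siPIPKIa replicate 5 (adjusted p = 0.079) or 6 (0.063) or siStarPap replicate 4 (0.063). On the arrays labelled siStarPap, PIP5K1A was 1.22-fold higher by the brightest probe set (adjusted p = 0.018), 1.27-fold higher by the middle one (adjusted p = 0.014) and at 0.980 of control by the dimmest (adjusted p = 0.80). The first of these lost its call without siStarPap replicate 5, at 0.23 on the log2 scale with an adjusted p of 0.059.

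**Figure D1:**
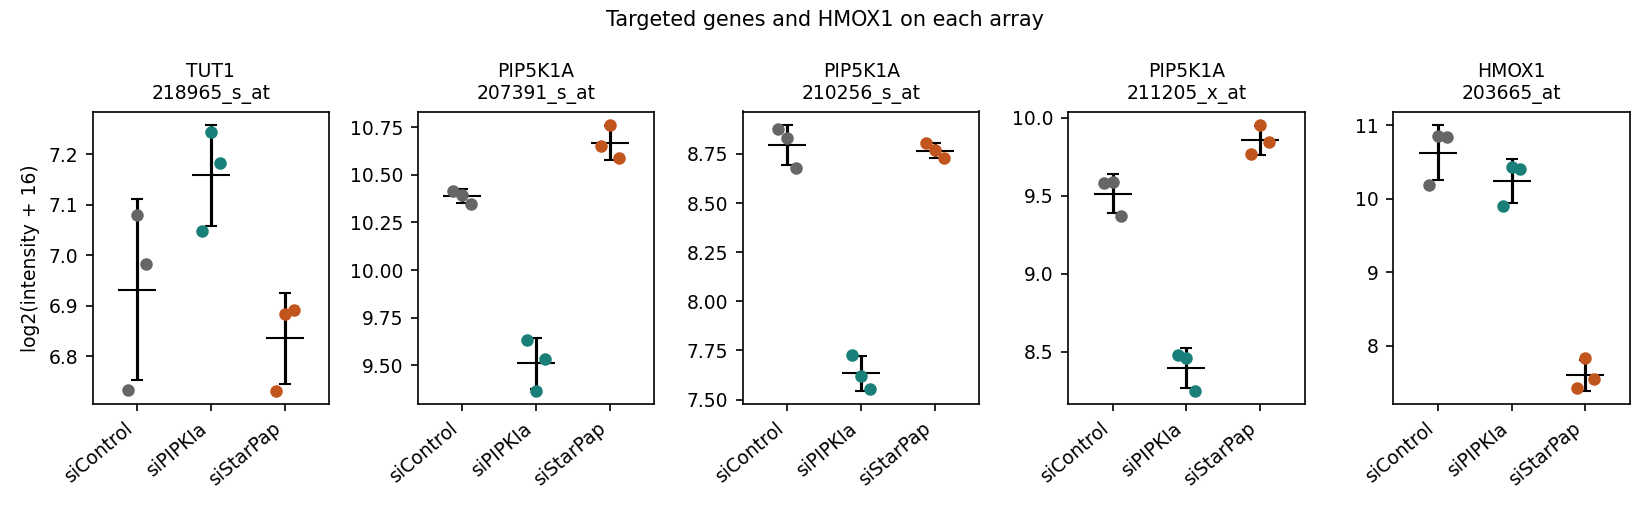
Level on the log2(intensity + 16) scale (vertical axes, which differ between panels and do not start at 0) of the TUT1 probe set, the 3 PIP5K1A probe sets (brightest, dimmest and the one between them) and HMOX1 in the 3 groups. Points are single arrays, bars are the mean and SD of 3 arrays; PIP5K1A is lowest on the siPIPKIa arrays, HMOX1 is lowest on those labelled siStarPap, and TUT1 overlaps between siControl and siStarPap.

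The arrays labelled siStarPap were compared with siControl, for the effect of an siRNA against Star-PAP. The chemokine genes CCL20, CXCL1 and CXCL2 were 21.7-fold, 16.6-fold and 11.3-fold lower, with log2 differences of -4.44 ± 0.24, -4.05 ± 0.21 and -3.50 ± 0.21. STC1, which encodes the hormone stanniocalcin, was at -3.58 ± 0.15. The histone genes H2BC21, H1-2 and H2AC6 changed by -4.17, -3.51 and -3.27 on the log2 scale. LGALS1 (galectin), ENO2 (a neuronal form of the glycolytic enzyme enolase) and RGS4 (a regulator of G protein signalling) changed by -3.42, -3.36 and -3.29. The largest rise was that of UGT8, which makes galactosylceramide, at 8.87-fold (3.15 ± 0.15). DSEL, ARL2, TPD52 and MACROD1 rose by 2.71, 2.69, 2.55 and 2.51, followed by CDH11, a cadherin, at 2.46, ELSPBP1 at 2.37, AGBL5 and LIX1L at 2.34 each and KHDC1 at 2.25. Adjusted p-values of these 20 genes, with n = 3 per group, were 2.4e-06 or lower.

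HMOX1, the haem-degrading enzyme, was 8.14-fold lower on the arrays labelled siStarPap, at -3.02 ± 0.19 (adjusted p = 3.4e-07). NQO1, a quinone reductase, was 3.50-fold lower at -1.81 ± 0.26 (adjusted p = 1.2e-04). GCLC, which starts glutathione synthesis, differed by 0.00 ± 0.08 (adjusted p = 1.0). HMOX1 and NQO1 belong to a list of NRF2-regulated genes, of which 4 rose, 7 fell and 12 of the 23 measured did not pass, with the same counts adjusted over the list alone. SRXN1 changed by -1.06 and TALDO1 by -0.86, and the median of the list was -0.14.

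In all, 7702 of 14626 genes (52.7%) passed the threshold in this comparison by limma, 3496 higher and 4206 lower. At least 2-fold changes were seen for 440 higher and 779 lower genes. The 3 arrays labelled siStarPap did not overlap with the 3 siControl arrays for 57.4% of genes, where chance gives 10%.

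Of the 34 gene lists, 5 passed camera, and none of the 34 with an estimated correlation between genes. Among 15 measured replication-dependent histones 12 fell and 0 rose (13 fell adjusted over the list alone), with a median of -1.74 (adjusted p = 1.7e-07, adjusted p = 0.55 with an estimated correlation). Without _s_at and _x_at probe sets 6 of 7 fell, with a median of -2.62 (adjusted p = 5.6e-04). H4C8 and H2BC4 changed by -2.89 and -2.98. Among 21 p53 targets 14 fell and 1 rose, the same adjusted over the list alone, with a median of -0.65 (adjusted p = 0.0026, adjusted p = 0.57 with an estimated correlation); with the mean of all probe sets the median was -0.30, and 12 of 20 fell. GDF15, a stress cytokine, changed by -1.61, TIGAR by -1.22 and POLH, a translesion polymerase, by -1.17. Of 21 interferon and double-stranded RNA response genes 15 fell (16 adjusted over the list alone) and 2 rose, with a median of -0.46 (adjusted p = 0.0056, adjusted p = 0.55 with an estimated correlation). OAS3 and IRF7 changed by -0.95 and -0.88, while EIF2AK2, the kinase PKR, rose by 0.62. Of 23 ATF4 and amino acid response genes 13 rose and 0 fell, the same adjusted over the list alone, with a median of 0.79 (adjusted p = 0.0056, adjusted p = 0.99 with an estimated correlation). SESN2 rose 3.99-fold and MTHFD2, of mitochondrial folate metabolism, by 1.45 ± 0.18 on the log2 scale. Of 33 cytosolic ribosomal proteins 22 rose (23 adjusted over the list alone) and 0 fell, with a median of 0.25 (adjusted p = 1.1e-05, adjusted p = 0.88 with an estimated correlation), RPL14 by 0.74 and RPS9 by 0.62; under quantile normalization the median was 0.16. By fry, which tests against no change, the ATF4 list did not pass (adjusted p = 0.12). It lost its camera call without siStarPap replicate 5, at a median of 0.48 (adjusted p = 0.051), and without _s_at and _x_at probe sets (adjusted p = 0.077). The interferon list lost its camera call in that last setting (adjusted p = 0.090). The 13 ATF4 rises became 21 without siStarPap replicate 4, 7 without replicate 5 or 6 and 20 with array weights.

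Knockdown of PIPKIα was compared with the same control arrays. ARL2, which encodes a small GTPase, rose 9.75-fold (3.29 ± 0.09) and UGT8 8.03-fold (3.01 ± 0.15). COQ9, of coenzyme Q synthesis, rose by 2.54, but probe sets without the _s_at and _x_at endings gave 0.15 (adjusted p = 0.20). SPRYD4 rose by 2.52, GALC, a lysosomal galactosylceramidase, by 2.49, MACROD1 by 2.46, CABLES2 by 2.40, LIX1L by 2.38, PBLD by 2.37 and NME4 by 2.31. H2BC21 was 13.6-fold lower (-3.77 ± 0.17), and STC1 and RGS4 changed by -3.66 and -3.65. GBP3, an interferon-induced GTPase, changed by -2.91, ATP9A by -2.85, ANKRD1 by -2.84, SPX by -2.77, CXCL1 by -2.71, CXCL8, the chemokine interleukin-8, by -2.62 and RAB39B by -2.55. Adjusted p-values of these 20 genes were 1.8e-06 or lower, with n = 3 per group.

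HMOX1 was at -0.38 ± 0.19 on the siPIPKIa arrays (adjusted p = 0.13), a value that moved to -0.60 and passed without siControl replicate 4 (adjusted p = 0.014). In the order of replicates 4, 5 and 6, its log2 level was 10.2, 10.8 and 10.8 on siControl arrays. It was 9.9, 10.4 and 10.4 on siPIPKIa arrays, lower at each number. Part of the error of 0.19 may thus be a spread shared by replicate number, so the missing call does not show that HMOX1 was unchanged on siPIPKIa arrays. NQO1 was 2.70-fold lower (-1.43 ± 0.26, adjusted p = 7.5e-04) and GCLC was at 0.11 ± 0.08 (adjusted p = 0.27). Of the 23 measured NRF2-regulated genes 8 fell and 1 rose (6 and 1 adjusted over the list alone), with SRXN1 lower by a log2 difference of -2.09 and KEAP1, the inhibitor of NRF2, higher by 0.67.

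By limma, 6772 genes (46.3%) passed, 3355 higher and 3417 lower, and 433 rose and 524 fell at least 2-fold. The arrays did not overlap for 55.8% of genes, where chance gives 10%. Lists past camera numbered 3, and 0 with an estimated correlation. Of the 15 histones 13 fell and 0 rose, the same adjusted over the list alone, with a median of -1.77 (adjusted p = 6.2e-08, adjusted p = 0.49 with an estimated correlation). Of the 21 p53 targets 11 fell and 2 rose, the same adjusted over the list alone, with a median of -0.34 (adjusted p = 0.022, adjusted p = 0.67 with an estimated correlation), and TP53INP1 and ZMAT3 changed by -1.59 and -1.34. Of the 33 ribosomal proteins 13 rose and 0 fell, the same adjusted over the list alone, with a median of 0.10 (adjusted p = 0.043, adjusted p = 0.81 with an estimated correlation). The p53 and ribosomal lists were lost without siControl replicate 4 (adjusted p = 0.064 for both, 2 lists past), and without _s_at and _x_at probe sets (adjusted p = 0.16 and 0.21). The ribosomal list was also lost under quantile normalization (adjusted p = 0.28), array weights (0.071), pseudocount 1 (0.056) and the 60th percentile filter (0.057), and without siPIPKIa replicate 4 (0.056) or 5 (0.060) or siStarPap replicate 5 (0.053). Under quantile normalization 8 ribosomal members rose and 1 fell. The number of lists was 5 without siPIPKIa replicate 6 and 6 without siStarPap replicate 4.

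**Figure D2:**
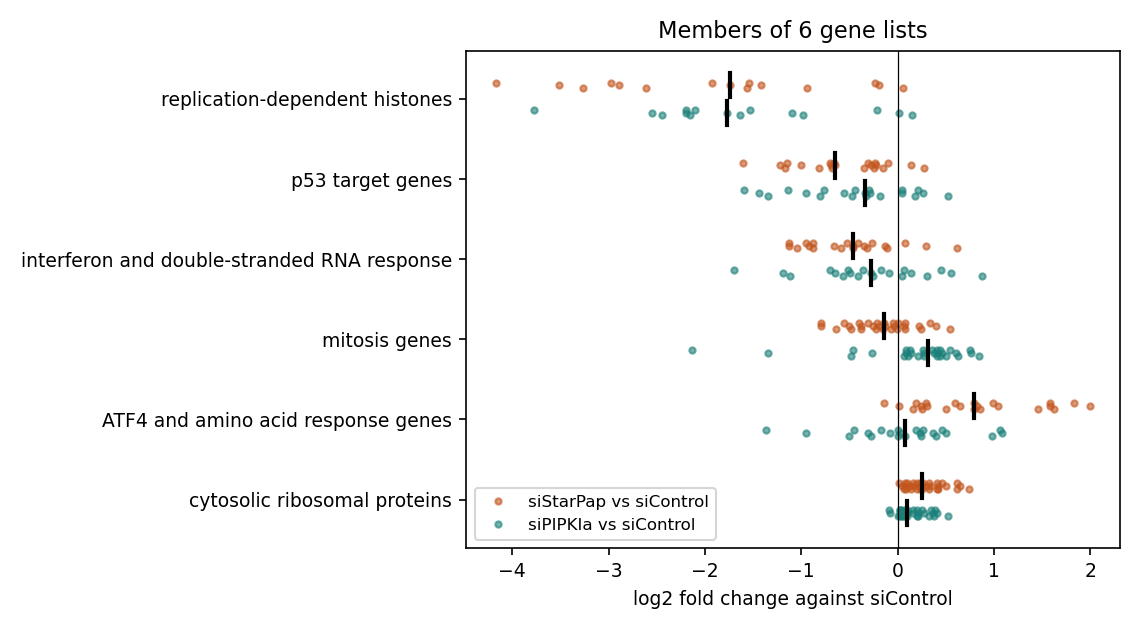
Log2 fold change against siControl (horizontal axis) of the measured members of 6 gene lists on the arrays labelled siStarPap and the siPIPKIa arrays. Each point is a gene and each black bar the median; histones lie at medians of -1.74 and -1.77 and the ATF4 list at 0.79 and 0.07.

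Whether the 2 siRNAs changed the same genes was asked next. UGT8, ARL2, MACROD1, LIX1L and NACC1 were the strongest rises in both, and NACC1 rose by 2.21 on the arrays labelled siStarPap and 2.23 on siPIPKIa arrays. H2BC21, STC1, RGS4, GBP3 and CXCL1 were the strongest falls in both, and GBP3 changed by -2.81 and -2.91. Of 4706 genes past the threshold in both comparisons, 4059 moved in the same direction, 1959 higher and 2100 lower. Independent lists of these sizes would share 801.93 higher and 982.63 lower genes. Simulated unchanged groups against 1 simulated control group shared at most 1. Those groups held no changed gene, so almost none could pass in either comparison. That count is therefore no baseline for lists of these sizes. Across genes, which are not independent replicates, the fold changes correlated at r = 0.597 (rho = 0.551), against a mean of 0.501 in simulations without effects. Their covariance was 0.178 against 0.0054 simulated, a difference of 0.172. With 3 controls the control group could not be split into parts of at least 2 arrays, and part of the excess may come from the shared controls. Of the 4059 genes 1745 also differed between the arrays labelled siStarPap and siPIPKIa.

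**Figure D3:**
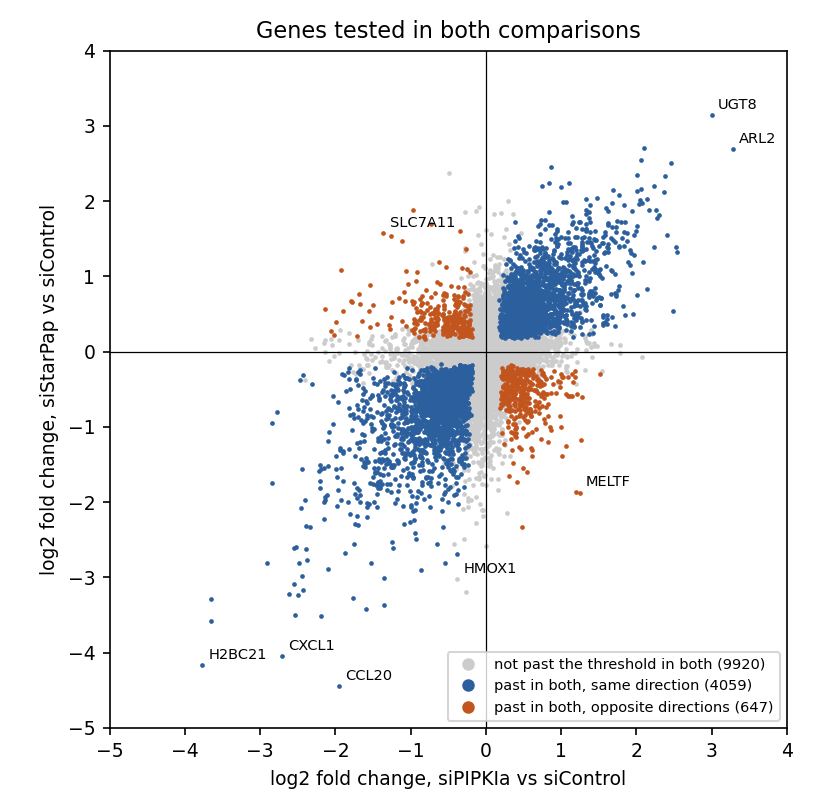
Log2 fold change against siControl of 14626 genes on the siPIPKIa arrays (horizontal axis) and the arrays labelled siStarPap (vertical axis). Each point is a gene; 4059 passed in both with the same direction, 647 passed in both with opposite directions, and grey points did not pass in both.

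In the direct comparison of the arrays labelled siStarPap with the siPIPKIa arrays, SPTSSA, a subunit of serine palmitoyltransferase, was higher by 3.02 ± 0.09, SLC7A11, the cystine transporter, by 2.94 ± 0.50, ELSPBP1 by 2.86, MPZL3 by 2.86 and CALU, a calcium-binding protein of the secretory pathway, by 2.79. MELTF differed by -3.12 ± 0.17, TMEM255A by -3.07, ZCCHC12 by -2.93, LYRM7 by -2.82 and HMOX1 by -2.64 ± 0.19. The limma adjusted p of these 10 genes was 5.6e-04 or lower. Against siControl, 647 genes passed in both comparisons in opposite directions. SLC7A11 was at 1.58 on the arrays labelled siStarPap and -1.36 on siPIPKIa arrays, CALU at 1.54 and -1.26, MELTF 3.66-fold lower and 2.38-fold higher, TMEM255A at -1.87 and 1.20 and COX20 at -1.17 and 1.27. The opposite calls of SLC7A11 did not hold in each leave-one-out fit: against siControl, siPIPKIa lost its call without any of siControl replicates 4, 5 and 6 or siPIPKIa replicates 4 and 5 (-1.03 to -1.44), and siStarPap without siControl replicate 6 or siStarPap replicates 5 and 6 (1.15 to 1.51). CALU turned to -0.48 on the arrays labelled siStarPap without _s_at and _x_at probe sets.

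In total 6692 genes differed directly (2906 higher, 3786 lower), 354 and 494 of them at least 2-fold. Of 30 mitosis genes 21 were lower and 3 higher on the arrays labelled siStarPap than on siPIPKIa arrays, the same adjusted over the list alone, with a median of -0.40 (camera adjusted p = 0.0083, adjusted p = 0.95 with an estimated correlation). Against siControl, 15 of them rose and 5 fell on siPIPKIa arrays (median 0.31, adjusted p = 0.056), and 4 rose and 9 fell on the arrays labelled siStarPap (median -0.15, adjusted p = 0.54). That median was -0.06 without siControl replicate 4 (7 rose, 10 fell), -0.22 without siStarPap replicate 4, -0.08 without siStarPap replicate 5, -0.10 with array weights and -0.06 without _s_at and _x_at probe sets, and the list passed in none of these. By fry, which tests against no change and passed 22 of the 34 lists, the siPIPKIa list had an adjusted p of 0.041. By camera it passed with array weights (adjusted p = 0.023), pseudocount 64 (0.043), the replicate block (0.047), only the groups compared (0.044), no filter (0.020) or the mean of all probe sets (0.044). It also passed without siControl replicate 4 (0.013), siPIPKIa replicate 6 (0.041) or siStarPap replicate 4 (0.048). BIRC5 and AURKB were lower by log2 differences of -0.92 and -0.51, whereas CCNB2 and TTK, lowered on siPIPKIa arrays, were higher by 2.13 and 1.35. Of the 23 ATF4 genes 10 were higher and 0 lower (12 and 0 adjusted over the list alone; median 0.64, adjusted p = 0.0083, adjusted p = 0.95 with an estimated correlation), and 7 ribosomal proteins were higher and 0 lower (4 and 0 adjusted over the list alone; median 0.13, adjusted p = 0.0089, adjusted p = 0.95 with an estimated correlation). By fry, against no change, the ATF4 list did not pass (adjusted p = 0.15). It lost its camera call without siStarPap replicate 5, with 4 higher, 1 lower and a median of 0.41 (adjusted p = 0.14). Without siStarPap replicate 4 it had 21 higher and a median of 1.11, with array weights it had 18 higher, without siPIPKIa replicate 5 it had 5 higher, and without siPIPKIa replicate 4 or siStarPap replicate 6 it had 4 higher. The 7 higher ribosomal proteins became 13 without siControl replicate 4 and 4 without siPIPKIa replicate 5 or 6. They numbered 17 with the mean of all probe sets, 16 with the intensity trend or array weights, 13 with pseudocount 64, and 11 with no filter or only the groups compared. Without _s_at and _x_at probe sets the mitosis (adjusted p = 0.22) and ATF4 lists (0.051) did not pass, nor did the ribosomal list under quantile normalization (0.059), and its median without _s_at and _x_at probe sets was 0.19.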

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

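The tests of swapped labels, S phase, gene-specific histone probe sets, control-array noise, siControl replicate 4 and the control group were chosen after the results were seen. The test of the TUT1 signal level and the counts of other array splits were set beforehand.

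Genes that differed directly between the arrays labelled siStarPap and siPIPKIa stood out by the limma test of that difference. SPTSSA (3.02), SLC7A11 (2.94), ELSPBP1 (2.86), MPZL3 (2.86) and CALU (2.79, negative against siControl without _s_at and _x_at probe sets) were higher on the log2 scale. MELTF (-3.12), TMEM255A (-3.07), ZCCHC12 (-2.93), LYRM7 (-2.82), HMOX1 (-2.64) and COX20 (-2.44) were lower. The mitosis list (median -0.40), the ATF4 list (0.64) and the ribosomal protein list (0.13) differed by camera, though not with an estimated correlation. Among values outside the comparisons, the bioB hybridisation control was higher on all 3 arrays labelled siStarPap than on the siControl arrays, by a mean of 0.21 on the log2 scale. Of the 5055 probe sets without a single gene symbol that were past the signal filter, 2085 passed the threshold on the arrays labelled siStarPap. That is a smaller share than the 52.7% of genes in the same comparison, but the 2 shares are not alike. The share of genes counts only the brightest probe set of each gene. With every named probe set past the filter counted by itself, 13974 of 27713 passed. Groups of 3 arrays were too small for the test of single deviating samples.

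TUT1 was not lower on the arrays labelled siStarPap. An exchange of labels with siPIPKIa is argued against by PIP5K1A, which was higher by 1.16 ± 0.07 on the arrays labelled siStarPap than on siPIPKIa arrays. A signal level at which these arrays register few changes is argued against by the 1252 genes within 0.25 of the TUT1 level. Of these 43.4% passed in either direction, against 52.7% of all genes tested, and 174 of the 1252 passed and were lower by at least 1.5-fold. Such counts do not show whether the TUT1 probe set itself lies above background. HMOX1, which the study names and so is not independent evidence, was 8.14-fold lower on the arrays labelled siStarPap, from 7.42 to 7.83 against 10.19 to 10.85 on siControl arrays, which goes with the label but does not exclude an exchange with samples outside the series. That exchange, signal of other transcripts on this one probe set, and loss of the protein without loss of the probed transcript stay open. Whether the siRNA lowered Star-PAP at all stays open too. The siRNA sequences are not in the labels, so effects on transcripts other than the target could not be tested. Changes on these arrays therefore cannot be assigned to loss of Star-PAP.

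Replication-dependent histones were lower in both comparisons. Fewer cells in S phase cannot be told apart from a histone-specific change: the S phase list had a median of -0.18 (95% bootstrap interval -0.49 to -0.01) on the arrays labelled siStarPap and -0.13 (-0.23 to 0.07) on siPIPKIa arrays, against -1.74 and -1.77 for histones, and how far other S phase genes should fall is not known here. Signal of one histone gene on shared probe sets, as the whole cause, is argued against by the 7 histone probe sets, of 7 genes, without _s_at and _x_at endings. In each comparison 6 of them fell, with medians of -2.62 (-2.98 to -0.94) and -2.10 (-2.45 to -1.09), below the -0.3 that this explanation allows; both medians also lie under -1, the bound set first, while the first interval reaches past it, and the -0.3 was taken for the whole interval after the values were seen. These bootstrap intervals resampled the genes or probe sets of a list, which are not independent of each other. They hold no spread between arrays. An effect of each siRNA's target on histone transcripts, which end without a poly(A) tail when processed normally, remains an untested alternative. Whether the labelled target held transcripts without a poly(A) tail was not tested here, so these values may not stand for all histone transcripts.

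Many genes changed alike in both comparisons. Chance values of the shared control arrays that are independent between genes are argued against by a covariance of 0.178, where the highest of 100 simulations reached 0.0059. The simulations drew the control arrays anew and held no deviation that runs across genes, so they cannot speak to a deviation of that kind. The deviating array siControl 4 is argued against by 4288 genes changed alike without it, compared with 4059. A property of the control siRNA or the control cells cannot be told apart from a shared effect of the siRNAs, since the design holds 1 control group. Processing of the control arrays was not tested and stays open: the cre hybridisation control was from 14.17 to 14.30 on the log2 scale there and lower, at 14.09 or less, on all 6 other arrays. Of 100 assignments of the 9 arrays to groups, only 1, the real one, gave as many genes changed alike (4059, highest other 2955). This excludes chance assignment only as far as the arrays are independent samples, which the labels do not say.

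A split of 6 arrays into groups of 3 can be made in 10 ways, too few for a share under 0.05. For genes changed, 1 split, the real one, reached the real count in each comparison: 7702 for siStarPap against siControl, 6772 for siPIPKIa against siControl and 6692 for the direct comparison, with 0 genes in the highest other split. For gene lists, 5 splits gave at least the real 5 lists for siStarPap (highest other 6) and 7 splits at least the real 3 for siPIPKIa (highest other 6). The number of lists past camera at the preset correlation thus did not set the real grouping apart from other splits.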

How the results depend on the processing

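For named genes, 1613 values under other settings kept their direction and side of the threshold, 13 lost the call, 9 gained one and 3 reversed. With each array left out, 1233 kept both, 31 lost the call and 5 gained one. The 2-fold threshold was chosen after seeing the data, and the cause of a change was not tested unless the setting's construction shows it. Leaving out each array gave 6686 to 7945 genes for siStarPap against siControl, 5693 to 7101 for siPIPKIa, 5560 to 7765 for the direct comparison and 3417 to 4288 for genes changed alike, 5 to 5 lists for siStarPap, 2 to 6 lists for siPIPKIa, -0.20 to -0.02 for TUT1 and -0.94 to -0.81 for PIP5K1A. In that order, the 4 gene counts were 3397, 2823, 2677 and 1426 at 1.5-fold, 1219, 957, 848 and 420 at 2-fold, and 13974, 12427, 12085 and 7251 with each probe set by itself, a count over more tests. Lists for siStarPap numbered 0 with an estimated correlation, 17 by fry (a test against no change) and 8 without a filter. Lists for siPIPKIa numbered 0 with an estimated correlation, 22 by fry, 5 with pseudocount 64, 5 with array weights, 5 with the replicate block, 6 with only the groups compared, 6 without a filter, 6 with the mean of probe sets and 1 without _s_at and _x_at probe sets. In that last setting CALU turned to -0.48 (siStarPap against siControl), CDH11 to -0.62 (siPIPKIa against siControl) and TPD52 to -0.28 (direct). Pairing by replicate number was not uniform. Of 9 same-numbered pairs 4 correlated above 0.1, in a range from -0.13 to 0.31. In 8 of 18 comparisons of an array with the 3 arrays of another group, it correlated best with its own number. The siPIPKIa and siStarPap pairs were at 0.31, 0.15 and 0.05. HMOX1 was lowest on replicate 4 of siControl (10.19), siPIPKIa (9.90) and siStarPap (7.42), so an effect shared by replicate number is not excluded. With the replicate block 4091 genes changed alike, against 4059. Dim probe sets have no detection call, which limits statements on low genes.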

Other observations

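The mRNA 3' end machinery list, with 23 members measured, did not pass camera in either comparison (adjusted p = 0.93 and 0.32). On the arrays labelled siStarPap 5 members rose and 4 fell, with a median of 0.06, and on siPIPKIa arrays 4 rose and 8 fell, with a median of -0.11. CPSF7, CSTF3, CSTF1, CSTF2T and PABPN1 were the 5 that rose on the arrays labelled siStarPap, by 0.69, 0.57, 0.36, 0.34 and 0.29, and were named after their values were seen. Of the 4 that fell, PAPOLA, the canonical nuclear poly(A) polymerase, changed by -1.41 on the arrays labelled siStarPap and by -0.47 on siPIPKIa arrays. PCF11 changed by -1.07 and -0.94, NUDT21, which guides choice of poly(A) site, by -0.90 and -1.07, and CSTF2 by -0.62 and -0.51. A further list was fixed as neuronal-lineage markers of HEK293 cells. It holds neurofilament genes and INA, but also PAX2, DES, VIM, GATA3, SOX2 and LIN28B, not all of which are neuronal. Of its 10 members 5 rose and 0 fell on siPIPKIa arrays (camera adjusted p = 0.053). On the arrays labelled siStarPap 4 rose and 2 fell (camera adjusted p = 0.54). LIN28B rose in both, by 1.11 on the arrays labelled siStarPap and 1.04 on siPIPKIa arrays, as did GATA3, by 0.82 and 0.51, and INA, by 0.50 and 1.15. NEFM was at 1.31 on siPIPKIa arrays and -0.24, not past, on the arrays labelled siStarPap, where NEFL and NEFH were at -0.68 each. Of 9 markers of other epithelial lines, 0 rose in either comparison, and 5 fell on the arrays labelled siStarPap (adjusted p = 0.14) and 4 on siPIPKIa arrays (adjusted p = 0.098). Of 17 cholesterol synthesis and uptake genes 3 rose and 9 fell on siPIPKIa arrays (adjusted p = 0.081), and 5 rose and 9 fell on the arrays labelled siStarPap (adjusted p = 0.57), so that the list passed in neither. STARD4 and HMGCS1 fell in both, at -2.03 and -1.34 on siPIPKIa arrays and -0.97 and -0.59 on the arrays labelled siStarPap, and SREBF2 rose in both, by 0.48 and 0.64. MSMO1 was at -1.68 on siPIPKIa arrays and 0.64 on the arrays labelled siStarPap. These members were picked after their values were seen.

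The chemokine genes CXCL1, CXCL2, CXCL8 and CCL20 were lower in both comparisons, and all are targets of the transcription factor NF-κB. A hypothesis formed from those values, that NF-κB targets in general may be lower, was tested on 25 other targets listed before their values were seen. Of the 21 measured, 14 fell and 1 rose on the arrays labelled siStarPap (median -0.57, limma camera adjusted p = 3.6e-04), and 14 fell and 2 rose on siPIPKIa arrays (median -0.50, adjusted p = 2.6e-04), adjusted over the 2 comparisons. With an estimated correlation the adjusted p was 0.057 in both, and neither passed. CCL2 changed by -1.83 and -1.97 and TNFAIP3 by -1.55 and -1.49, while TNIP1 rose by 0.81 and 0.59. A higher level in the control cells gives the same values and stays open.

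Some genes had probe sets that moved apart by at least 2-fold in each direction, a count made after the data were seen. This held for 9 genes on the arrays labelled siStarPap and 9 on siPIPKIa arrays, 3 of them shared, among 371 and 334 genes with at least 2 such probe sets. On the arrays labelled siStarPap they included RAB40B, at 1.39 ± 0.08 for one probe set and -1.46 ± 0.08 for the other, and ICE2, with the widest gap, at 1.22 ± 0.08 and -1.84 ± 0.16. The choice of probe set also mattered without a fold minimum. When _s_at and _x_at probe sets were left out, 84 of 6170 siStarPap calls against siControl were called in the opposite direction. For siPIPKIa these were 82 of 5468 calls. The call and direction were kept for 91.0% and 90.2%.

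The control probe set for 28S ribosomal RNA had an intensity from 4136 to 5511 on siPIPKIa arrays, below the 6893 to 8158 on siControl arrays, and from 6098 to 11426 on the arrays labelled siStarPap. The mean of the bio and cre hybridisation controls was from 11.15 to 11.25 on siPIPKIa arrays, from 11.26 to 11.30 on siControl arrays and from 11.30 to 11.43 on the arrays labelled siStarPap, on the log2 scale.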
